A study of Mus musculus with 4 samples.

How the data were processed

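Gene expression was profiled by paired-end RNA sequencing in 4 libraries of B16, an established mouse melanoma cell line. The labels place 2 libraries in an adherent group, grown attached in medium with 20% fetal calf serum, and 2 in a sphere group, which the labels call passage 1 mammospheres. The spheres grew for 7 days in serum-free medium in low-attachment flasks. That medium held bFGF and EGF at 20 ng/ml each, insulin at 5 µg/ml, and albumin at 0.4%. Total RNA was made into libraries with an unstranded kit, per the labels' protocols, so reads from overlapping genes on opposite strands cannot be told apart.

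The deposited values are raw counts. Per the series' design text, the authors mapped reads with STAR 2.3.0e and made exon-level counts with the script of DEXSeq 1.6.0 on the UCSC mm9 annotation. They then collapsed these counts to gene level with a DEXSeq function and tested them with DESeq2 1.0.19, selecting genes by a false discovery rate under 0.1 and an absolute log2 fold change above 1. The submitters' processing notes list STAR 2.3.0, DESeq2 1.0.19 and mm9. Because exon-level counts were summed, a fragment that covers several exon bins can add more than 1 count to its row. Column totals are therefore totals of counts, not of reads, and intervals that assume independent counts would be too narrow.

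The table has 28232 rows, of which 16326 carry a single UCSC transcript ID and 11906 carry several IDs joined together. None of the 55419 different IDs is paired with a gene name in the file, and 0 of them matched the gene name tables at hand. Names were not inferred from the IDs or their order, so rows are given by ID, with no coordinates or annotation. Before the data were examined, 33 gene lists with 851 entries had been fixed, together with a rule for naming genes. One part of the rule asked for a call and a gene symbol. Another asked for a fixed set of genes whether called or not, among them Mitf, Tyr, Dct, Ngfr and Vegfa. The lists needed gene names too, so neither the rule nor the lists gave any gene to report. The planned list tests (limma camera and fry) were not run.

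Column names show the growth condition but not the replicate number of the labels. Columns were assigned to groups only, and the libraries are called A2 and A4 (adherent) and S2 and S4 (spheres), after the last digit of their column names. What that digit stands for is not given in the sources used here. The column names also carry another unexplained number, which is the same within a growth condition and differs between them. Whatever it stands for cannot be told apart from growth condition. No column was left unused. The design text speaks of 2 independent experiments per condition.

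Counts were tested with edgeR 4.0.16 in R 4.3.3. Rows were filtered with filterByExpr, normalised with TMM factors and compared between spheres and adherent cells with the quasi-likelihood F test with robust dispersion estimates, with growth condition as the only term. Benjamini-Hochberg adjusted p-values under 0.1 were called. Standard errors are the log2 fold change divided by the square root of F. CPM values (counts scaled to a common library size) use TMM-scaled totals, and ratios between libraries use log2 CPM with a prior count of 2. The test was also tested on simulated data: negative binomial counts with the means and library sizes of the real rows and 200 rows changed by known folds.

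Alternatives fixed before the data were examined were DESeq2 size factors, library totals alone, no filter on low counts, DESeq2 1.42.0 with its default Wald test, a threshold of 0.05, the study's own selection rule, and each library left out in turn. After the data were seen, a block by the last digit of the column names was added, as were comparisons of each pair of libraries and of the 3 possible splits of the 4 libraries into groups of 2. Plots were drawn with matplotlib 3.10.9.

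Total counts were 82775631 in A2, 68483942 in A4, 127865382 in S2 and 86527802 in S4. A count of 0 allows up to 3 counts, which corresponds to between 0.023 and 0.044 CPM in these libraries, for counting error only.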

Results

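The data comprised 4 RNA sequencing libraries of B16 mouse melanoma cells, 2 from adherent cultures (A2 and A4) and 2 from passage 1 spheres (S2 and S4). Sphere culture without attachment and serum is used to enrich tumour cells with stem-like properties, and the series' title places the comparison in a search for vaccination targets on such cells in melanoma. Total counts per library ranged from 68483942 in A4 to 127865382 in S2. Of the 28232 rows, 8610 were at 0 in every library, and 14822 (52.5%) passed the filter on low counts. The median count of the tested rows lay between 1395 in A4 and 2683.5 in S2. The 10 most abundant rows took 6.96% of counts in A2, 7.13% in S2, 9.30% in A4 and 10.1% in S4. Rows carry transcript IDs without gene names, so the changes below are given for rows and not for named genes or pathways.

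The main comparison asked which genes differ between spheres and adherent cells. No row differed at an adjusted p under 0.1 in edgeR's quasi-likelihood test (0 of 14822, n = 2 libraries per group). This test counts the difference between last digits of the column names, which both groups share, as variation within groups. Its p-values can therefore be too large. An even spread of p-values would put 741 rows under 0.05, and a smaller number is no evidence that the groups are alike. At an unadjusted p under 0.05 the same test gave 25 rows, 2 higher and 23 lower in spheres. That division into higher and lower rows changed with the library left out. With a block by the last digit of the column names it was 39 higher and 55 lower. The study's own tool, in a later version, gave the same count. DESeq2's Wald test called 0 of 19622 rows at an adjusted p under 0.1, with or without the added rule of an absolute log2 fold change above 1, and 285 rows had an unadjusted p under 0.05. Both sphere libraries lay on the same side of both adherent libraries in 16.1% of rows, 1273 higher and 1119 lower in spheres. Libraries with no structure among them would give 33.3%.

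The fit does not show that spheres and adherent cells are alike. The 95% interval of the log2 fold change reached a median of 1.13 to either side of the estimate over the tested rows, and 0.93 over the 10412 rows with a mean of at least 5 CPM. The biological coefficient of variation within groups was 44.4%. In simulated data with that variation, the test recovered 2% of rows changed 2-fold, 40% of those changed 4-fold, 86% of those changed 8-fold and 100% of those changed 16-fold, with 50 rows at each fold. With a simulated coefficient of variation of 0.1 it recovered 100% of the rows changed 2-fold, also with 2 libraries per group. The simulated libraries varied independently, with the same coefficient for every row and nothing shared between libraries of the same last digit. These shares therefore do not give the power of the test on the real libraries, nor that of a fit with a block by last digit. The design text calls the libraries of a group independent experiments.

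As no row was called and rows carry no gene names, no genes could be chosen by the rule fixed beforehand. The genes it asked for whether called or not could not be found among the rows. The 4 rows given here were chosen after their values were seen, as the largest differences with both groups apart and at least 5 CPM in the higher group. The row uc007apt.1+uc007aps.1 had 1.80 ± 0.010 CPM in adherent cells and 5.13 ± 4.67 CPM in spheres (mean ± SD, n = 2 each), a log2 fold change of 1.51 (SE 0.83) with an edgeR adjusted p of 1. Its sphere mean rested on S4, with 8.43 CPM against 1.83 CPM in S2. The row uc007nyp.1+uc007nyo.1 had 2.39 ± 0.189 CPM in adherent cells and 6.52 ± 5.23 CPM in spheres, again with S4 at 10.2 CPM and S2 at 2.83 CPM. Without S4, the log2 fold changes of these rows were 0.03 and 0.25, and without S2 they were 2.14 and 2.01.

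In the other direction, uc008nxx.1+uc008nxy.1+uc008nxw.1+uc008nxz.1 had 14.5 ± 15.6 CPM in adherent cells and 2.61 ± 0.134 CPM in spheres, a log2 fold change of -2.48 (SE 0.96) with an edgeR adjusted p of 1. The row uc007tat.1 had 8.38 ± 9.17 CPM in adherent cells and 1.53 ± 0.326 CPM in spheres. Both adherent means rested on A4, with 25.6 and 14.9 CPM against 3.53 and 1.89 CPM in A2. Without A4, the log2 fold changes were -0.44 and -0.32, without A2 they were -3.32 and -3.33, and with the block by last digit they were -1.87 and -1.82.

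Libraries of the same growth condition were less alike than libraries whose column names end in the same digit. The spread of the log2 ratio over tested rows, as a median absolute deviation scaled to an SD, was 0.74 between A2 and A4 and 0.76 between S2 and S4. It was 0.17 between A2 and S2 and 0.51 between A4 and S4. The remaining pairs had 0.77 (A2 and S4) and 0.73 (A4 and S2). More than 2-fold differences were found in 3443 rows between A2 and A4 and in 3561 between S2 and S4, against 229 between A2 and S2 and 2254 between A4 and S4. Pearson's r of log2 CPM across rows, which are not independent replicates, was 0.996 for A2 and S2, 0.963 for A4 and S4, and between 0.951 and 0.955 for the remaining 4 pairs. The first principal component, with 66.2% of the variance, placed A2 and S2 at -55.1 and -54.0 and A4 and S4 at 49.5 and 59.7. The second, with 30.5%, placed A4 at 54.8 and S4 at -49.9.

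**Figure D1:**
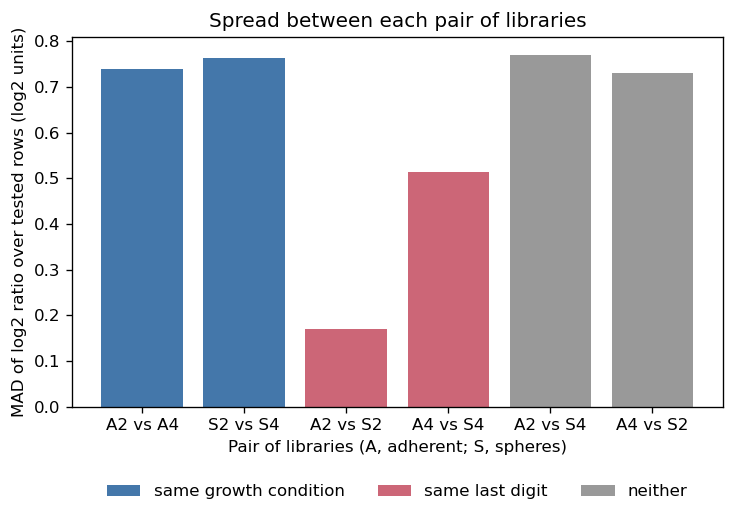
The bars give the scaled median absolute deviation of the log2 ratio over 14822 tested rows (log2 units, vertical axis from 0) for each pair of libraries, coloured by whether the pair shares its growth condition, the last digit of its column names, or neither. A2 and S2 (0.17) and A4 and S4 (0.51) lie below the other pairs, which lie between 0.73 and 0.77.

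Because of this structure, spheres and adherent cells were also compared within each last digit, with 1 library on each side and therefore no test. Among the 10412 rows with at least 5 CPM, 3 were more than 2-fold higher in S2 than in A2 and 0 were more than 2-fold lower. Between S4 and A4, 255 such rows were more than 2-fold higher in spheres and 481 were more than 2-fold lower. The log2 ratios of the pairs showed little relation across these rows, with a Pearson's r of -0.06 and a Spearman's rho of -0.10, and had the same sign in 45.6% of rows. Over all 14822 tested rows, r was 0.03, 23 rows were more than 2-fold higher in spheres in both pairs where independent lists would share 8.9, and 35 were lower in both where 8.1 would be shared. Another 39 rows passed 2-fold in opposite directions, where independent lists would give 17.8. The numbers for independent lists pool rows of all abundances. Between A2 and S2, 135 tested rows passed 2-fold upward and 94 downward, but only 3 and 0 of those with at least 5 CPM. Such differences thus lay almost only in rows of low abundance, and pooling makes the numbers for independent lists too low. The excess over them was not tested within a level of abundance and cannot be read as agreement between the pairs. Among the rows with at least 5 CPM, 0 passed 2-fold the same way in both pairs and 1 passed in opposite directions.

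**Figure D2:**
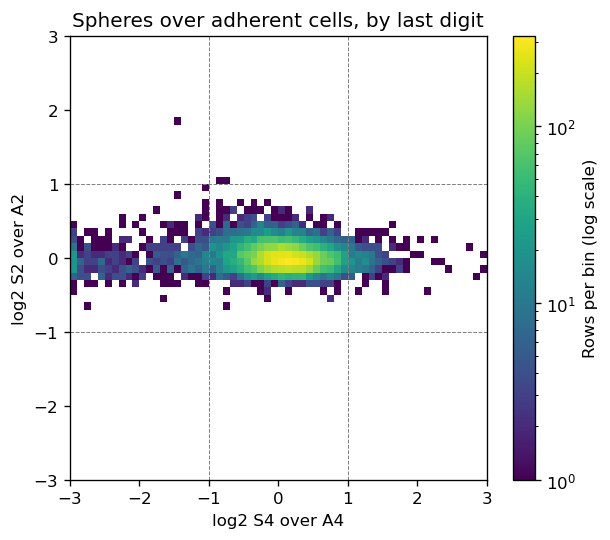
Each cell counts rows with a mean of at least 5 CPM (10412 rows, colour on a log scale) by the log2 ratio of spheres to adherent cells between S4 and A4 (horizontal) and between S2 and A2 (vertical), with ratios beyond the axes placed in the outermost cells and dashed lines at 2-fold. The ratios of S2 to A2 lie close to 0 while those of S4 to A4 spread past 2-fold in 255 rows upward and 481 downward.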

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

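The count of changed rows was also 0 under the 9 alternatives that could have added rows: DESeq2 size factors, library totals alone, no filter on low counts, DESeq2, each of the 4 libraries left out, and the block. The other 3, a threshold of 0.05 and the study's fold change rule with either tool, only tighten a selection that already held 0 rows. The number of rows with an unadjusted p under 0.05 did depend on the setting. It was 29 with DESeq2 size factors, 27 with library totals and 113 of 19622 without the filter. It changed more widely than this with the library that was left out. In the fits that leave out 1 library, the lone library of its group is assumed to vary like the other group. These fits and the fit with the block have 1 residual degree of freedom and untested power, so they cannot show that the count is stable. The columns carry no replicate number of the labels, so the planned pairing by that number could not be made. A replicate block by the last digit of the column names, added after seeing the data, gave 0 rows at an adjusted p under 0.1 and 94 at an unadjusted p under 0.05, and lowered the coefficient of variation from 44.4% to 26.9%. Deviations from the group means correlated at 0.60 across rows between libraries with the same digit. With 2 libraries per group the deviations mirror each other, so both pairs give the same value by construction. That value restates the grouping by last digit, and is a hint from the data and not from the design. The adjusted p of the 4 rows given by ID lay between 0.998 and 1 in every refit. The share of rows separated by the last digit stayed between 66.0% and 69.6%, and that separated by growth condition between 13.6% and 16.2%, with DESeq2 size factors, with rows of at least 5 CPM, after thinning, and without the 100 most abundant rows. The alternatives planned for gene lists were not run, since rows carry no gene names.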

Other observations

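The tests of a shared batch and of exchanged libraries were chosen after the result was seen; the test of depth was written before its result was seen. The 4 libraries can be split into 2 groups of 2 in 3 ways. The split by growth condition called 0 rows in edgeR's quasi-likelihood test at an adjusted p under 0.1 (25 at an unadjusted p under 0.05), the split by the last digit of the column names called 4379, and the remaining split called 0 (14 at an unadjusted p under 0.05). With 3 splits no share under 0.05 can be reached. The call count of the split by last digit restates the closeness of libraries with the same digit. That structure does not follow the growth condition as the columns name it. Rows with both libraries of one side above both of the other made up 66.2% for the last digit, 16.1% for growth condition and 17.6% for the remaining split; these shares add up to the whole, so a high share for one split lowers the others.

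After all libraries were thinned to the smallest total, 66.0% of rows were still separated by the last digit. Median counts of the tested rows were at least 1395, so thinning would reorder few rows and this share cannot decide. Totals compared after the data were seen argue against sequencing depth as the source of this pattern. A2 and S4 had similar totals (82775631 and 86527802) but the widest spread of the log2 ratio, 0.77. A2 and S2 had less similar totals (82775631 and 127865382) but the narrowest, 0.17. A4 and S2, with the smallest and largest totals, had 0.73. A shared experiment or batch may account for the grouping by last digit. The larger spread within a digit was 0.51, below the smallest between digits, 0.73, but these values are the pattern itself and add no support. An exchange of an adherent and a sphere library (A4 with S2, or A2 with S4) may account for this grouping too. It would make the split with 4379 calls the split by growth condition, but that count is also the pattern itself and adds no support. In that case the comparisons of spheres with adherent cells given above would not be comparisons of growth conditions. These explanations cannot be told apart here, because no label ties the digit to a batch and no named marker row identifies a library; a biological difference between the independent experiments also stays open and untested.

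The pairs with the same digit were themselves unequal. Between A2 and S2, 1.5% of tested rows differed more than 2-fold, and between A4 and S4 15.2% did. With 1 library on each side, that contrast was not tested.

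Single libraries also stood apart in some rows, a count made after seeing the data. Among the 10412 rows with a mean of at least 5 CPM, 54 were more than 4-fold higher in A4 than in each of the other libraries, and together they took 0.55% of the counts of A4. S4 had 6 such rows above the others and 64 more than 4-fold below each of them. A4 had 2 rows below the others, and A2 and S2 had 0 in either direction. Without gene names, no cell type or pathway was tested for these rows.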
